A study of Mus musculus with 6 samples.

How the data were processed

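RNA of 6 libraries of MA-10 mouse Leydig tumour cells was compared, 3 of wild-type sublines and 3 of Tspo mutant sublines made with CRISPR-Cas9 and grown with G418. Per the labels' protocols, total RNA was taken with TRIzol at 80% confluence and made into stranded libraries after depletion of ribosomal RNA. The genome build was NCBIM37, per the submitters' processing notes. The aligner, the quantification tool, the annotation release, the strand setting and the way reads were divided between near-identical copies are not given in the sources used here. The treatment text in the labels mentions a cAMP analogue, and no label says that any of these libraries was treated.

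The deposited series table gives a log2 value per coding segment and library, and its column names end in the suffix of an alignment file, per the file headers. What the values are was worked out from the deposited values themselves. The deposited log2 value equals the log2 of the aligned bases in a segment times a scale factor per library, and a segment with 0 bases stands at 0.9 base, so that every library has its own lowest value. Undoing this gave base totals that were whole within 0.01 for 99.2% to 99.3% of the non-zero segments under 20000 bases, and the commonest totals were 100 and 200 bases, a read length of 100. The basis of the authors' scale factor is not given in the sources used here. The values are not divided by segment length, and 99.9% of the segments had the position of a coding segment, stop codon included, of GENCODE vM1. Gene symbols and identifiers of 22582 of the 22605 genes matched that annotation. Strand is given for each gene, but without the strand setting reads of antisense and overlapping genes cannot be told apart. The deposited lists of higher and lower segments give 1 log2 difference per segment with no value per library, and of the higher and lower differences 80.1% and 80.7% equalled the log2 ratio of bases pooled over the 3 libraries of each group plus a constant of 0.112, within 0.001. The test or threshold behind the authors' lists is not given in the sources used here, and 8 further segments of the higher list were not used here.

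Base totals are not read counts, so no count model was fitted between the genotypes and the planned one was replaced by the test planned for log2 values. Depth was between 12798264 and 15260575 read lengths per library. A total of 0 allows up to 3 read lengths, or 300 bases, by counting error only. The median segment length was 121 bases. Each gene was represented by the coding segment with the highest mean over the 6 libraries, and genes at the lowest value in 4 or more libraries were left out, which left 15173 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), on the log2 values as deposited, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05, two-sided. Each adjusted p of a gene or segment in the text comes from limma, and each adjusted p of a gene list from camera. Because a segment with 0 bases stands at 0.9 base, differences of genes near the floor depend on that value. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used to read the tables and to draw plots.

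Before the data were examined, the groups, the test, the filter, the 1 row per gene, 22 gene lists, markers of 7 cell types and the rule for named genes were fixed, with alternatives for each. The named genes were Tspo, 12 fixed genes of steroid synthesis and the TSPO complex, the 6 higher and 6 lower genes with the largest differences among those that passed, had groups apart and a mean at or above the median of tested genes, and in each list the 2 rising and 2 falling members with the largest differences among those that passed. Other members named in the text were picked after their values were seen, as examples of a list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 28 lists that had tested genes.

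Replicates were compared by a chi-square per gene, over 10604 genes with at least 2000 bases in every library. The bases of the segment that stands for the gene were divided by the expected overlap of a 100-base read with it. This overlap was the mean squared overlap over the mean overlap, so it depends on segment length. Replicates 1 and 2 of both genotypes differed by no more than sampling noise and were counted once in every mean ± SD. Fits with these replicates averaged into 1 sample, with and without the replicate number as a block, were added after seeing the data. Pairing by replicate number was checked on the deviations from the group means over genes at or above the median level. The correlations across genes, which are not independent replicates, were 0.287, 0.284 and 0.397 for replicates 1, 2 and 3, each above the 0.1 used for this check. Wild-type replicate 1 correlated with mutant replicate 2 at 0.379 and wild-type replicate 2 with mutant replicate 1 at 0.275. Replicate 3 of a genotype correlated with replicates 1 and 2 of the other at -0.313 to -0.38. Deviations within a group sum to 0, so the check only sets replicate 3 against the others. It cannot pair replicates 1 and 2 by number. The labels name no shared day or batch.

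The procedure was tested on simulated data for this comparison, with 15173 genes, 5 runs and 200 changed genes per run. With 6 libraries simulated as independent, it recovered 53% of 2-fold and 73% of 4-fold changes, and 6.4% of its calls were false. Changed genes were not simulated with near-identical replicates, so these shares do not carry over to the calls made here. Simulated data with near-identical replicates and no change gave 0 to 7 calls with 6 libraries (median 0) and 0 to 3 with replicates counted once, assuming that genes vary independently. Alternatives covered the replicate block, leaving out each library, the filter, an added pseudocount of 1, the scaling, the moderation of limma, the row that stands for a gene, and a test against a fold of 1.2.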

Results

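The libraries were made from MA-10 cells, a mouse Leydig tumour line that makes steroids. They compared wild-type sublines of this line with sublines in which Tspo had been edited with CRISPR-Cas9 (Tspo mutant). Tspo codes for the translocator protein of the outer mitochondrial membrane, and the study asked how its loss changes the expression of nuclear genes. Total RNA depleted of ribosomal RNA was sequenced in 3 libraries per genotype. The values were aligned bases for each of 232396 coding segments of 22605 genes, and the 6 libraries held between 12798264 and 15260575 read lengths of 100 bases, with the fewest in mutant replicate 3 and the most in wild-type replicate 3. Between 69.6% and 72.0% of the segments had bases in a library. The 13 mitochondrially encoded coding segments and all 222 segments of chromosome Y were listed at 0 in every library, so these genes could not be compared.

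Replicates 1 and 2 of the wild type differed by no more than sampling noise, with a mean chi-square per gene of 1.006 (SE 0.018), and replicates 1 and 2 of the mutant differed by less than it, at 0.807 (SE 0.031). Replicate 3 differed from them by 5.54 and 6.81 in the wild type and by 5.69 and 5.92 in the mutant. Replicates 1 and 2 of each genotype were therefore counted as 1 sample, and each mean ± SD is over n = 2 samples per group, the mean of replicates 1 and 2 and replicate 3. The test was fitted on the 6 libraries, as fixed before the data were examined, so its p-values count near-identical libraries as independent and are too small. The log2 differences come from that fit and can differ slightly from the difference of the printed means. No label says that the replicates were separate cultures, and p-values then measure only the spread between these libraries, which may be technical. The first principal component (46.5% of the variance) separated the genotypes, and the second (33.8%) separated replicate 3 of both genotypes from the other libraries.

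Tspo itself was read first. Tspo (ENSMUSG00000041736) lies on the plus strand of chromosome 15 (NCBIM37), and its first coding segment was lower in the mutant while its other coding segments were not. The first coding segment, 83401844 to 83402025 in exon 2, holds the start codon and stood at 17.01 ± 0.083 (log2, SD, n = 2) in the wild type and at 15.84 ± 0.0014 in the mutant. The difference was -1.18 (SE 0.062), which left 44.0% of the wild-type level, with an adjusted p of 0.00514 (limma, every segment tested as its own row). The lowest wild-type library stood at 16.95 and the highest mutant library at 15.89. The adjusted p was 0.361 with replicates 1 and 2 counted once, and 0.135 with the replicate number as a block as well. The second segment, 83402630 to 83402768 in exon 3, differed by -0.02 (SE 0.054, adjusted p = 0.861). The last segment, 83404200 to 83404388 in exon 4, differed by 0.06 (SE 0.064, adjusted p = 0.645) and stands for Tspo in the gene-level test, because its mean over the 6 libraries was the highest of the 3. The authors' deposited table lists the first segment as lower in the mutant by 1.43 on the log2 scale. The position of the edit is not given in the labels used here, so a segment outside it says nothing about the genotype of a library.

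**Figure D1:**
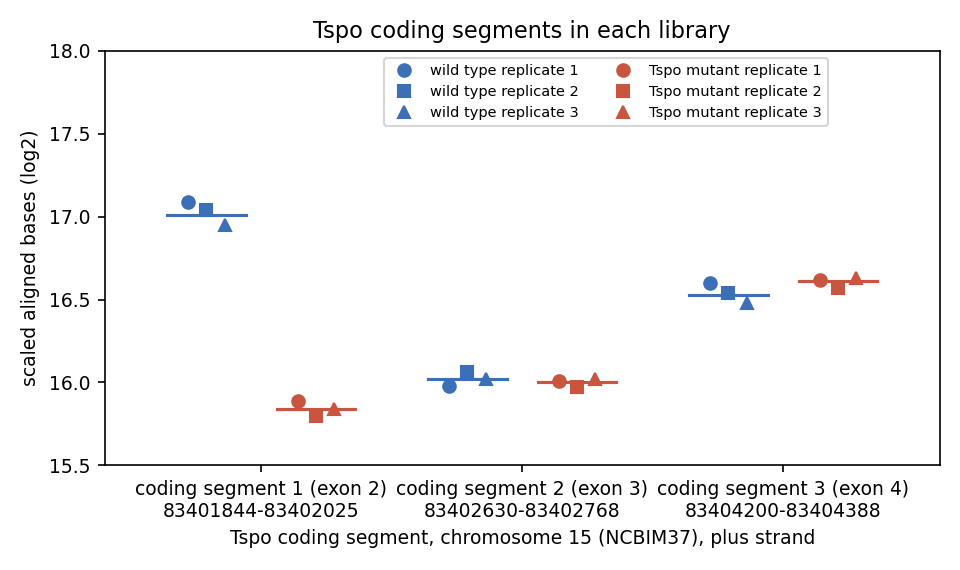
Scaled aligned bases (log2, vertical axis) of the 3 Tspo coding segments (horizontal axis) in each library; symbols are single libraries and lines are means with replicates 1 and 2 counted once. In the first segment the wild-type libraries lie at 16.95 to 17.09 and the mutant libraries at 15.80 to 15.89, while the other segments overlap.

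Of 15173 genes tested between Tspo mutant and wild type, 171 rose and 74 fell in the mutant (limma, adjusted p below 0.05), and 79 and 47 of these did so by at least 2-fold. The largest rises among well-expressed genes were in Tgm3, a transglutaminase, Fam78a, Ush1g, Cebpe, a transcription factor of the C/EBP family, S1pr1, a sphingosine-1-phosphate receptor, and Casp1, the inflammasome caspase. The largest falls were in Hspa1a, an inducible heat shock protein of the Hsp70 family, Tex19.2, Bai2, an adhesion G protein-coupled receptor, Hsd3b1, an enzyme of steroid synthesis, Caskin1 and Chdh, the choline dehydrogenase of mitochondria. With replicates 1 and 2 counted once, limma called 0 genes (lowest adjusted p = 0.0724, 1208 genes at an unadjusted p below 0.05). With the replicate number as a block as well, 24 genes passed, 14 higher and 10 lower, and 18 of them were among the 245. That fit leaves almost no residual degrees of freedom, so its p-values rest mostly on the spread that limma borrows from other genes. The replicate block on all 6 libraries called 532 genes, 373 higher and 159 lower. Leaving out replicate 3 of the wild type or of the mutant raised the count to 758 and 771, and leaving out wild-type replicate 1 or 2 or mutant replicate 1 or 2 lowered it to 16, 25, 15 and 7. Fits without replicate 3 of a genotype have only near-identical libraries in that group, so their p-values, here and below, are smaller still than those of 6 libraries. The tested genes had a median difference of 0.08 (log2), and other scalings moved the split: quantile normalization gave 144 higher and 168 lower genes, and trimmed-mean centring gave 131 and 132.

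Tgm3 stood at 14.64 ± 0.40 in the wild type and 16.78 ± 0.33 in the mutant, a difference of 2.15 (SE 0.195, adjusted p = 0.00666). Fam78a differed by 2.04 (SE 0.135, adjusted p = 0.00274), and Cebpe by 1.69 (SE 0.0707, adjusted p = 0.00046), the gene with the lowest p of the comparison. S1pr1 was higher by 1.52 (SE 0.134) and Casp1 by 1.44 (SE 0.120). Ush1g was higher by 1.80 (SE 0.299, adjusted p = 0.0391). Hspa1a went from 18.55 ± 0.11 to 15.98 ± 0.98, a difference of -2.78 (SE 0.346, adjusted p = 0.0186). Bai2 differed by -1.64 (SE 0.142), Caskin1 by -1.44 (SE 0.151) and Chdh by -1.22 (SE 0.180). Tex19.2 differed by -2.37 (SE 0.331, adjusted p = 0.0268). Tgm3, Fam78a, Cebpe, S1pr1, Hspa1a, Bai2 and Caskin1 were among the 24 genes that passed with replicates counted once and the replicate block. On the same samples without the block, 0 genes passed. Leaving out wild-type replicate 1 or 2 or mutant replicate 1 or 2 ended 15, 13, 14 and 17 of the 19 calls among all named genes, and Fam78a and Cebpe passed whichever single library was left out. Hspa1a, Tex19.2 and Hsd3b1 have related genes, and the sequences of these pairs were not compared here. How reads were divided between genes of like sequence is not given in the sources used here. Hspa1b differed by -0.31 (adjusted p = 0.394) and Hsd3b6 by 0.10 (adjusted p = 0.482), while Tex19.1 fell by 1.69 (adjusted p = 0.0453). The values of these 3 pairs are uncertain as far as they share reads, which was not tested.

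**Figure D2:**
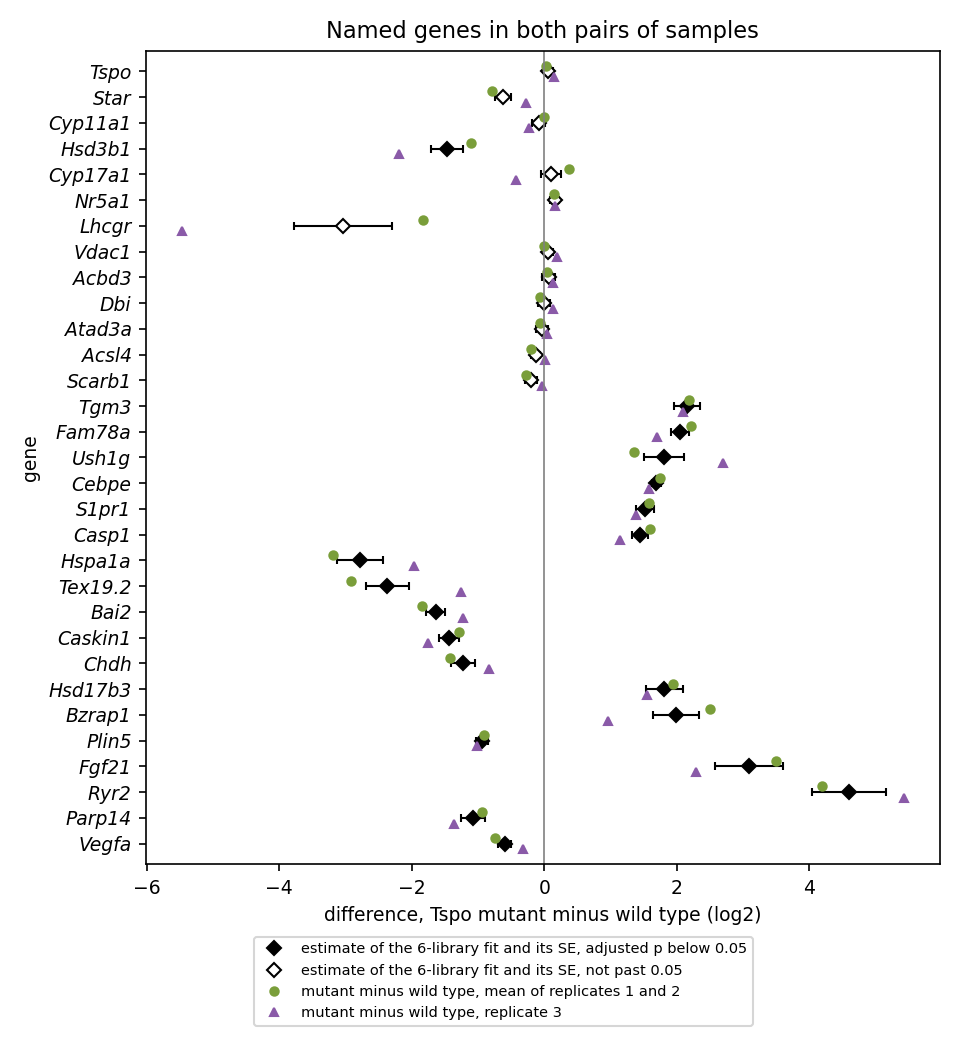
Difference between Tspo mutant and wild type (log2, horizontal axis) of the 31 genes named by rule (vertical axis); diamonds with SE bars are the fit on 6 libraries, filled where the adjusted p was below 0.05 (19 genes), circles are replicates 1 and 2 and triangles replicate 3. Among all 31 genes, Lhcgr has the widest gap between circle and triangle.

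Genes of steroidogenesis moved in both directions. Of 27 tested members, 1 rose, 1 fell and 25 did not pass, and adjusted over the list alone 1 rose and 3 fell. Hsd3b1, which converts pregnenolone to progesterone, fell from 18.13 ± 0.10 to 16.49 ± 0.66 (difference -1.47, SE 0.238, adjusted p = 0.0361). Hsd17b3, which makes testosterone from androstenedione, rose from 12.63 ± 0.28 to 14.38 ± 0.56 (difference 1.81, SE 0.281, adjusted p = 0.0332). Both calls ended without any one of replicates 1 and 2 of either genotype, with adjusted p of 0.118 to 0.139 for Hsd3b1 and of 0.0916 to 0.166 for Hsd17b3. Star, which brings cholesterol to the inner mitochondrial membrane, differed by -0.62 (SE 0.124, adjusted p = 0.0600). It passed the threshold with the replicate block (adjusted p = 0.0468) and when adjusted over the list alone. With replicates 1 and 2 counted once the adjusted p of Star was 0.539, and 0.215 with the same block as well. It reached 0.548 over all alternatives. Without mutant replicate 3 the mutant group holds only near-identical libraries, which count as 1 sample, so no p-value of that fit is given. Lhcgr, the luteinizing hormone receptor, differed by -3.04 (SE 0.739, adjusted p = 0.0920) and passed when adjusted over the list alone. Its size depended on mutant replicate 3, which stood at 10.53 against 12.84 and 13.61 in mutant replicates 1 and 2. The difference was -2.14 without mutant replicate 3, -3.68 without mutant replicate 2 (adjusted p = 0.157) and -1.96 by the median over segments (adjusted p = 0.202). Cyp11a1, the side-chain cleavage enzyme, differed by -0.08 (SE 0.0964, adjusted p = 0.684), Cyp17a1 by 0.10 (SE 0.157, adjusted p = 0.754) and Nr5a1, the steroidogenic transcription factor SF-1, by 0.16 (SE 0.0722, adjusted p = 0.294). As a set the list was lower than the other genes (camera, adjusted p = 0.0149), but not with an estimated correlation (adjusted p = 0.822 with an estimated correlation) or without wild-type replicate 3 (adjusted p = 0.0640).

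Genes of proteins described as partners of TSPO at the mitochondrion were mostly not separated between the genotypes in RNA level. Of 25 tested members of that list, 1 rose, 0 fell and 24 did not pass, and adjusted over the list alone 1 rose and 1 fell (camera, adjusted p = 0.691). Bzrap1, the gene of a TSPO-associated protein, rose by 1.99 (SE 0.347, adjusted p = 0.0441), and trimmed-mean centring ended that call (adjusted p = 0.0583), as did leaving out any one of replicates 1 and 2 of either genotype (adjusted p = 0.146 to 0.187). Lonp1, a mitochondrial protease, differed by -0.35 (SE 0.0769) and passed only when adjusted over the list alone. Vdac1 differed by 0.06 (SE 0.0691), Acbd3 by 0.07 (SE 0.0959), Dbi by -0.0005 (SE 0.0908), Atad3a by -0.03 (SE 0.0910) and Acsl4 by -0.13 (SE 0.0706), with adjusted p between 0.369 and 0.999. The 76 tested nuclear genes of oxidative phosphorylation included 0 that passed, also when adjusted over the list alone, with a median difference of 0.07 and 2 genes at an unadjusted p below 0.05 (camera, adjusted p = 0.691). Without mutant replicate 2 this list passed camera as higher (adjusted p = 0.0305). None of the tested genes of the tricarboxylic acid cycle (22, camera adjusted p = 0.774), of fatty acid oxidation (27, camera adjusted p = 0.887), of glycolysis (22, camera adjusted p = 0.691) or of mitochondrial dynamics, biogenesis and mitophagy (28, camera adjusted p = 0.691) passed in limma, over all genes or adjusted over the list alone, and 1, 2, 2 and 4 of them had an unadjusted p below 0.05. Glycolysis passed camera as lower without wild-type replicate 3 (adjusted p = 0.0372). The mitochondrially encoded genes were listed at 0.

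Among the genes of sterol synthesis and uptake and of lipid droplets, Plin5 alone passed over all genes. None of the 30 tested genes of sterol synthesis and uptake passed, also when adjusted over the list alone (5 at an unadjusted p below 0.05), and the list as a set was lower than other genes (median -0.03, camera adjusted p = 0.0414, and 0.885 with an estimated correlation). The replicate block ended this camera call (adjusted p = 0.0511), as did counting replicates 1 and 2 once (adjusted p = 0.250) and leaving out wild-type replicate 2 (0.132), mutant replicate 1 (0.124) or mutant replicate 2 (0.213). Idi1 of the mevalonate pathway differed by -0.48 (SE 0.151), the low density lipoprotein receptor gene Ldlr by -0.41 (SE 0.133) and the high density lipoprotein receptor gene Scarb1 by -0.20 (SE 0.0863, adjusted p = 0.268). Of 30 tested genes of lipid droplets and fatty acid synthesis, 1 fell and none rose, over all genes and adjusted over the list alone (camera, adjusted p = 0.691). That gene was Plin5, a lipid droplet protein of oxidative tissues, which went from 16.25 ± 0.063 to 15.29 ± 0.14 (difference -0.94, SE 0.0901, adjusted p = 0.00798). Its adjusted p was 0.0550 to 0.0657 without any one of replicates 1 and 2 of either genotype.

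Lists of stress and antioxidant genes were lower than other genes in camera at the preset correlation, and not with an estimated one. Of the 34 tested genes of the antioxidant response 26 were lower and 8 higher, with a median of -0.11, and none passed alone, also when adjusted over the list alone (5 at an unadjusted p below 0.05). The set was lower than other genes in camera (adjusted p = 0.000197, and 0.822 with an estimated correlation). Srxn1, which reduces oxidized peroxiredoxins, differed by -0.49 (SE 0.108, adjusted p = 0.0723), and Slc7a11, a cystine transporter, by -0.38 (SE 0.105, adjusted p = 0.117). None of the 21 endoplasmic reticulum stress genes passed, also when adjusted over the list alone (2 at an unadjusted p below 0.05), and that set was lower (median -0.08, camera adjusted p = 0.0149, and 0.822 with an estimated correlation). Dnajb9, a chaperone of that compartment, differed by -0.48 (SE 0.113, adjusted p = 0.0851). In the integrated stress response and mitochondrial unfolded protein response list, 1 of 36 tested genes rose and none fell, and adjusted over the list alone 1 rose and 1 fell. The riser was Fgf21, a secreted stress hormone, from 10.55 ± 0.68 to 13.44 ± 0.17 (difference 3.09, SE 0.519, adjusted p = 0.0407, and 0.0659 to 0.187 without any one of replicates 1 and 2 of either genotype). Wild-type replicate 2, at 9.34, held under 300 bases of Fgf21, the amount that a total of 0 allows. The size of the Fgf21 difference is therefore uncertain. That set was lower than other genes (camera adjusted p = 0.0149, and 0.885 with an estimated correlation) although 18 of its genes were higher and 18 lower, and its mean was 0.04. With replicates 1 and 2 counted once the camera calls of these last 2 lists ended (adjusted p = 0.0786 for endoplasmic reticulum stress and 0.0865 for the integrated stress response), as they did without mutant replicate 2 (0.137 and 0.213). Camera compares a list with all other tested genes, and in 11 of the 28 tested lists, this one included, the median or mean had another sign than camera's direction.

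The next list held targets and parts of the cAMP pathway, through which luteinizing hormone acts on Leydig cells. None of its 29 tested members passed over all genes (11 at an unadjusted p below 0.05), and adjusted over the list alone 1 rose and 6 fell. The 6 were the immediate early genes Egr1 (difference -1.37, SE 0.262), Fosb (-1.46, SE 0.426), Junb (-0.41, SE 0.119) and Dusp1 (-0.39, SE 0.113), the cAMP-responsive modulator Crem (-0.57, SE 0.163) and Lhcgr (-3.04), and the riser was the scaffold gene Akap12 (0.74, SE 0.197). Egr1 had an adjusted p of 0.0536 over all genes, of 0.0331 with the replicate block and of 0.125 with that block and replicates 1 and 2 counted once. The set was lower than other genes (camera adjusted p = 0.0149, and 0.822 with an estimated correlation), but not without wild-type replicate 3 (adjusted p = 0.0853) or mutant replicate 1 (adjusted p = 0.0589). No library is described as treated with a cAMP analogue in the labels of the samples.

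The other signalling lists did not pass camera on the 6 libraries, and without wild-type replicate 3 hypoxia response (adjusted p = 0.00148) and extracellular matrix and adhesion (adjusted p = 0.0375) passed as lower. Calcium handling had 1 riser among 27 tested genes and adjusted over the list alone 2 risers and 1 faller (camera, adjusted p = 0.691). The riser was Ryr2, a calcium release channel, from 8.19 ± 0.37 to 12.99 ± 0.50 (difference 4.60, SE 0.555, adjusted p = 0.0173). Its difference was 9.93 by the median over segments, 5.29 by their sum and 3.68 with a pseudocount of 100 bases. Each wild-type library held under 300 bases of Ryr2, the amount that a total of 0 allows, so the size of its difference is uncertain. Apoptosis had 1 riser among 26, Casp1, and adjusted over the list alone 2, with Casp7 at 0.41 (SE 0.0905) as the second (camera, adjusted p = 0.252). Hypoxia response had 1 faller among 18, the growth factor gene Vegfa (difference -0.60, SE 0.0950, adjusted p = 0.0349), and 2 adjusted over the list alone, with Epas1 at -0.82 (SE 0.177; camera, adjusted p = 0.138). Interferon-stimulated genes had 1 faller among 24, Parp14 (difference -1.08, SE 0.182, adjusted p = 0.0408), and 2 adjusted over the list alone, with Isg15 at -0.69 (SE 0.165; camera, adjusted p = 0.262). NF-kB targets and inflammatory mediators had none among 22 and 1 riser adjusted over the list alone, Nfkbia at 0.64 (SE 0.137; camera, adjusted p = 0.861). Without any one of replicates 1 and 2 of either genotype the adjusted p was 0.0588 to 0.126 for Ryr2, 0.129 to 0.158 for Vegfa and 0.132 to 0.161 for Parp14, and that of Casp1 was 0.0748 without mutant replicate 2. Extracellular matrix and adhesion had none among 29 and 1 riser adjusted over the list alone, Col4a2 at 3.16 (SE 0.587; camera, adjusted p = 0.191). None of the 35 cell cycle genes (camera adjusted p = 0.443) and 24 genes of AMPK and nutrient sensing (camera adjusted p = 0.315) passed, also when adjusted over the list alone, and 2 and 5 of them had an unadjusted p below 0.05.

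Markers of other cell types were read beside these lists. The 5 tested markers of adrenal cortex, a steroid tissue that shares genes with Leydig cells, were all lower, none passed over all genes, and adjusted over the list alone 1 fell, Cyp11b1 (difference -1.25, SE 0.313). That set was lower than other genes (camera adjusted p = 0.0149, and 0.822 with an estimated correlation), but not without mutant replicate 2 (adjusted p = 0.0613). Leydig markers had 1 riser and 1 faller among 11, Hsd17b3 and Hsd3b1, and adjusted over the list alone 2 rose and 3 fell (camera, adjusted p = 0.491). Of 9 tested Sertoli markers none passed, also when adjusted over the list alone (camera adjusted p = 0.0638, and 0.822 with an estimated correlation). That set passed camera as lower with the replicate block (adjusted p = 0.0413) and without wild-type replicate 3 (adjusted p = 0.0375), but not with replicates 1 and 2 counted once (adjusted p = 0.165, and 0.0819 with the block). Of 7 tested peritubular or fibroblast markers, 6 were higher, with a median of 1.45, and none passed, also when adjusted over the list alone (camera, adjusted p = 0.415). Their levels were low and scattered, with Col3a1 at 6.73 ± 3.41 in the wild type and 12.18 ± 1.29 in the mutant. None of the tested markers of macrophages (4, camera adjusted p = 0.691), endothelium (5, camera adjusted p = 0.691) and germ cells (4, camera adjusted p = 0.846) passed, also when adjusted over the list alone.

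Genes of chromosome 17 were lower in the mutant as a group. Among the 7587 tested genes at or above the median level, the 398 on chromosome 17 had a median difference of -0.17 (bootstrap SE 0.013), and 86.2% were below 0. Their median lay -0.24 (log2) from that of the other chromosomes, a ratio of 0.844. The next lowest were chromosome 14 at -0.05 and chromosome 5 at -0.003, whose medians lay -0.12 and -0.07 from those of the other chromosomes. Chromosome 14 was shifted in both pairs of samples, by -0.102 in replicates 1 and 2 and by -0.144 in replicate 3. Of the 74 genes that fell, 26 lie on chromosome 17, which holds 5.19% of the tested genes, and 1 of the genes that rose lies there. Of the 31 genes named by rule, Hspa1a, Caskin1, Plin5, Vegfa and Lhcgr are on chromosome 17, each with a difference larger than this shift. Plin5 and Vegfa were also the only members of their lists that fell over all genes. The chromosomes of other list members given as examples are not given here. Some of them may lie on chromosome 17 too, so part of a small fall of such a member may be this shift.

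**Figure D3:**
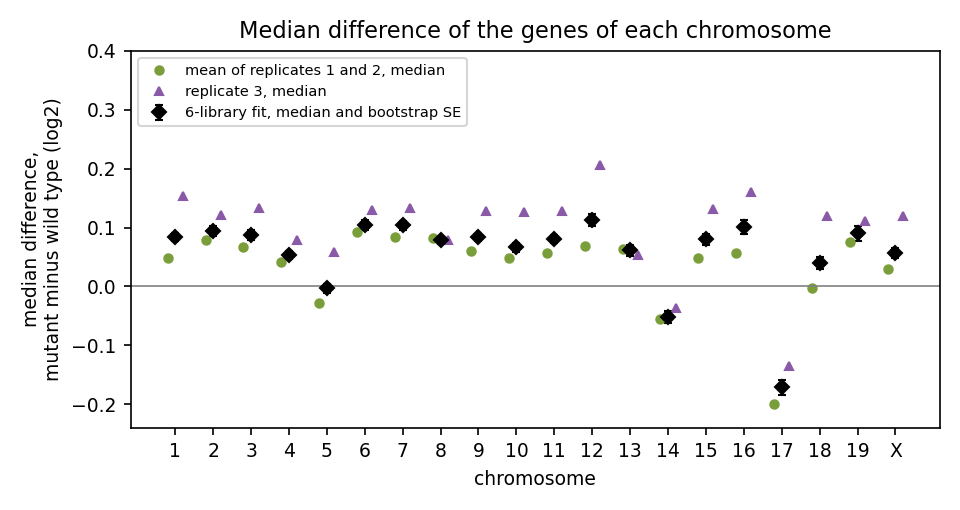
Median difference between Tspo mutant and wild type (log2, vertical axis) of tested genes at or above the median level, by chromosome (horizontal axis); diamonds are the fit on 6 libraries with bootstrap SE, circles replicates 1 and 2, triangles replicate 3. Chromosome 17 lies lowest by all 3 symbols, with diamonds at -0.17 for it and -0.05 for chromosome 14.

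The authors' deposited lists of higher and lower segments were compared with these calls. The list of higher segments analysed here held 20065 segments of 5798 genes and the list of lower segments had segments of 3878 genes, with a smallest difference of 1.18. In the higher list 44.8% of the segments had bases in 1 library only and 54.6% had at most 200 bases over all libraries, and in the lower list these shares were 44.2% and 55.2%. Of the listed segments, 1034 higher and 513 lower ones stood for a gene tested here, and 68 and 32 of them passed in the same direction. Pooling the libraries in all other 9 splits into 3 and 3 gave 26414 to 29471 segments past a difference of 1.18, against 32882 for the split by genotype.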

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

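Counting near-identical replicates once, taking replicate 3 as a block, the pseudocount of 100 bases, the minimum of 1000 bases and summing segments were chosen after seeing the data; the other alternatives were planned. Against 245 genes that differed and 126 that differed by at least 2-fold, the replicate block called 532 and 193, replicate 3 as a block 1423 and 385, every segment as its own row 869 and 637, a pseudocount of 100 bases 400 and 205, and the sum over segments 435 and 209. Near-identical replicates counted once gave 0 and 0 (limma, 1208 genes at an unadjusted p below 0.05), with the replicate block 24 and 23, and the sum over segments counted once 1 and 1. Without single libraries the counts ranged from 7 to 771 and from 6 to 304. The test against a fold of 1.2 called 66 genes. The number of libraries does not account for the counts without single libraries. These rose to 758 and 771 without replicate 3 of the wild type or the mutant and fell to 7 to 25 without any other. Without replicate 3, the group of that genotype holds only libraries as close as sampling noise (mean chi-square per gene 1.006 in the wild type, 0.807 in the mutant). The spread in that group is then too small, so the higher counts are not a more reliable result. The cause of the other shifts was not tested. Of the 7 gene lists, 0 passed with an estimated correlation and 0 with fry, which asks another question. With near-identical replicates counted once 4 passed, also with the replicate block and with summed segments, namely steroidogenesis, antioxidant response, cAMP response and adrenal cortex markers. Without single libraries 4 to 9 lists passed. Without mutant replicate 2, endoplasmic reticulum stress, the integrated stress response, sterol synthesis and adrenal cortex (adjusted p = 0.0613) did not pass, and oxidative phosphorylation passed as higher (0.0305). Steroidogenesis and cAMP response did not pass without wild-type replicate 3 (0.0640 and 0.0853), cAMP response and sterol synthesis without mutant replicate 1 (0.0589 and 0.124), and sterol synthesis without wild-type replicate 2 (0.132). Without wild-type replicate 3, glycolysis, hypoxia response, extracellular matrix and Sertoli markers passed as lower. Steroidogenesis did not pass after quantile normalization or by the median over segments (0.0552 and 0.0579), nor endoplasmic reticulum stress by that median (0.0643). Tspo, at 0.06 by its last segment, turned to -0.40 by the sum over its segments (adjusted p = 0.0291), because the sum takes in the lower first segment. With replicates 1 and 2 counted once the sum called 0 genes as lower, so that Tspo call ended. By the median over its segments Tspo stood at -0.54 (adjusted p = 0.0182). That median was the last segment in each wild-type library and the second segment in each mutant library. These segments themselves differed by 0.06 and -0.02 between the genotypes, so the -0.54 compares unlike segments. The overlap with the authors' lists was 100 genes, 627 at an unadjusted p below 0.05 and 15 at an adjusted p below 0.01. Of the named genes, 19 lost their call with replicates counted once, 12 with the replicate block as well, 10 in limma without the trend, 4 with every segment as its own row, 2 by the median over segments, 1 by their sum and 1 with trimmed-mean centring, and 15, 13, 14 and 17 without wild-type replicate 1 or 2 or mutant replicate 1 or 2 (Hsd3b1 at an adjusted p of 0.118 to 0.139). None but Tspo changed direction past the threshold, and the replicate block changed only the call of Star, which also passed after quantile normalization and trimmed-mean centring. Among lists the replicate block changed only sterol synthesis and Sertoli markers. Count models and other pseudocounts for linear values were not run, and no gene was tested between the genotypes on recovered reads, since the values are base totals on a log2 scale. Depth limits genes with few bases, where the 0.9 base that stands for 0 sets the difference.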

Other observations

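The tests of the explanations below were chosen after the patterns were seen, except those on GC content and length and on other splits of the libraries. Among the 24 genes that passed with replicates counted once and the replicate block, several had low levels in wild-type cells and higher ones in the mutant. The p-values of that fit rest mostly on the spread borrowed from other genes, and without the block 0 genes passed. Micalcl stood at 12.22 ± 0.45 in the wild type (difference 4.78, adjusted p = 0.00359), Hspb8, a small heat shock protein, from 8.98 ± 0.017 to 14.78 ± 0.14 (difference 5.80, adjusted p = 0.0492), Mylk, the myosin light chain kinase, from 11.90 ± 0.71 to 15.37 ± 0.25 (difference 3.47, adjusted p = 0.0492), and Gas1, a membrane protein of growth-arrested cells, from 12.13 ± 0.36 to 15.35 ± 0.24 (difference 3.22, adjusted p = 0.0492). The wild-type mean of Hspb8 lay under 300 bases, the amount that a total of 0 allows. The size of its difference is therefore uncertain, and its small SD is no measure of precision. Klf15, a metabolic transcription factor, was higher by 3.25 (adjusted p = 0.0466), and Emb, a chaperone of monocarboxylate transporters, by 1.76 (adjusted p = 0.0309). Defb19, a defensin, was lower by 3.72 (log2 difference -3.72, adjusted p = 0.0492), the vasopressin receptor gene Avpr1a differed by -1.73 (adjusted p = 0.0492), the receptor gene Gpr35 by -1.36 (adjusted p = 0.0492) and the endotoxin receptor gene Tlr4 by -1.43 (adjusted p = 0.0139). These genes were picked after their values were seen.

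Lists of energy metabolism passed camera between replicate 3 of both genotypes and replicates 1 and 2. Of 76 nuclear genes of oxidative phosphorylation, 72 were higher in replicate 3 (median 0.13), as were all 22 tested genes of the tricarboxylic acid cycle (median 0.13), while 18 of 22 glycolysis genes (median -0.20) and 14 of 18 hypoxia response genes (median -0.31) were lower. Of their members 1, 1, 3 and 3 passed alone in limma. The sizes differed by genotype. In the wild type the medians were 0.07 for oxidative phosphorylation, 0.07 for the tricarboxylic acid cycle, -0.31 for glycolysis and -0.43 for hypoxia response. In the mutant they were 0.15, 0.18, -0.08 and -0.11. Camera gave adjusted p of 1.17e-07, 0.000191, 0.00164 and 0.00377 for these lists, and 0.871 for each with an estimated correlation. Fatty acid oxidation was also higher (camera adjusted p = 0.0249, and 0.871 with an estimated correlation), but not with replicates 1 and 2 counted once (adjusted p = 0.0736). The copper transporter gene Atp7b differed by -2.82, the cell cycle inhibitor gene Cdkn1a by -1.24, the class I antigen gene H2-T23 by -1.40 and the kallikrein gene Klk1 by 2.70. In the fit on 6 libraries 883 genes passed for this term, 275 higher and 608 lower, and 1 with replicates 1 and 2 counted once (1886 at an unadjusted p below 0.05). Sequencing depth is argued against, since replicate 3 was 7.04% deeper than the mean of the others in the wild type and lay at -12.0% from it in the mutant. A swap of the replicate 3 libraries between genotypes is argued against by the first Tspo segment, which in wild-type replicate 3 lay at -0.115 (log2) from the wild-type mean of replicates 1 and 2. A shared day or culture condition may account for the pattern, since the deviations of both replicate 3 libraries correlated at 0.397 across genes, but the labels name no day or batch and it cannot be told apart from other differences between these samples. No biological explanation was tested.

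The first Tspo coding segment was lower in the mutant and the other coding segments were not. A lower level of the whole transcript is argued against by the mean difference of the second and last segments, 0.0188 (log2). Reads that cross an edited site may fail to align, and loss of all 100-base reads over a single site would take this 182-base segment down to -1.15 at the lowest, against an observed -1.18 (SE 0.062). The value lies at that bound within its error, which is consistent with loss of reads around an edit. A deletion of part of the segment, skipping of exon 2 and a mixture of edited and unedited cells stay open and were not tested.

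Genes of chromosome 17 were lower in the mutant in both pairs of samples. After a fit on GC content and segment length over all 7587 genes, the shift from the other chromosomes was -0.255 (SE 0.012) against -0.245 before, so these do not account for it. It was -0.252 in replicates 1 and 2 and -0.248 in replicate 3, which argues against a single replicate as its source. A candidate explanation is a difference in the copy number of chromosome 17 between the sublines that were compared, for which 100% of the 9 bins of 10 Mb with at least 10 genes lay below the median of the other chromosomes. This hypothesis was found and tested on the same data, an effect of the Tspo edit on these genes stays open, and DNA was not analysed here. The smaller shift of chromosome 14 (-0.121) was not put to these tests.

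The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these splits 1, the real one, gave as many as 245 genes, with 0 as the highest of the others, and 1 gave as many as 126 genes with at least a 2-fold difference, again with 0 as the highest of the others. For gene lists, 4 of the 10 splits gave 7 or more, with 10 as the highest of the others. Among the 3 other splits that part every same-numbered pair, the number of genes was 0 and that of lists 0 to 10. In the 3 other splits with at least 7 lists, the near-identical mutant replicates stood on the same side, which points to a structure of the samples.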
